A study of Mus musculus with 36 samples.

How the data were processed

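RNA from the small intestine of 36 female C57BL/6 JOlaHsd mice was sequenced as bulk libraries, 1 per mouse. The labels gave 4 groups of 9 mice in a design that crossed diet (a control diet or a clover diet) with infection by H. polygyrus (none, or about 300 larvae by gavage). The labels placed 3 cages of 3 mice in each group but did not say which mouse lived in which cage, so no cage term could be fitted and mice sharing a cage were treated as independent. The deposited file held raw read counts per gene symbol, 1 column per library, which the authors had not normalized. GRCm39 was the genome build and DESeq2 the tool named by the authors; the aligner, the counting tool and the annotation were not given in the sources used here. Of 20122 lines in the file, 8 held annotation text without counts and were left out. The remaining 20114 genes included 2349 with a count of 0 in every library. Genes were used by symbol and no genome coordinates are given, because the annotation at hand was of an earlier build. Immunoglobulin and T cell receptor constant genes were not analysed here.

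Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups with a minimum count of 10, which left 15149 genes, and libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with 1 mean per group was fitted to all 36 libraries, with robust dispersion estimates. It was tested two-sided for 7 contrasts, which were infection under each diet, diet in uninfected and in infected mice, the interaction of diet and infection, and the average effect of each factor. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, with no threshold on fold change. Log2 fold changes are given ± SE. Expression levels are counts-per-million (CPM) with TMM scaling, given as the mean ± SD of the 9 libraries of a group. Scores of gene lists and the infection score used log2 CPM with a prior count of 2. A gene with no counts in the reference group was given a lower bound against a floor of 3 counts over the whole group, and one with 1 to 3 counts a ratio with its 95% interval. These bounds and intervals cover counting error only.

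Before the data were examined, 40 gene lists were fixed by symbol. They covered epithelial cell types, immune cells, nutrient and xenobiotic metabolism, stress responses, other tissues that a piece of gut could hold, and regions of the gut. Each was tested by camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 40 lists of a contrast, and also with an estimated correlation and by fry. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move on balance in 1 direction. The genes named in the text were chosen by a rule fixed at the same time. For each contrast it took the 6 highest and the 6 lowest log2 fold changes among genes that passed, had at least 1 CPM on average in 1 of the groups compared and carried a symbol that was not a predicted or clone name. It added up to 4 members with the smallest p of each list that passed camera. Where fewer than 12 genes passed, it took all of them and the 5 with the smallest p. Members of a list that did not pass are given as values. Genes outside this rule are named as chosen after their values were seen. A gene that the rule took is not reported here.

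An infection score was computed for each library over the genes that passed for the average infection effect, as the mean centred log2 CPM of rising genes minus that of falling genes. Its shift was compared between diets by 100000 permutations of the diet labels within each infection state, and within infected mice by an exact permutation test of 9 against 9, both two-sided. In the exact test each score stayed centred on the uninfected mean of its own diet. List scores were compared by exact permutation tests, and scores adjusted for a covariate by permutation of residuals. The test was also run on simulated counts for the diet contrast in infected mice. Of genes changed 1.5-fold it recovered 77.6%, of those changed 2-fold 88.1% and of those changed 4-fold 98.5%, with 7 false calls, and it made 0 calls where nothing had been changed. A list shifted 1.3-fold gave an adjusted p of 4.28e-11 by camera and 1.87e-07 with an estimated correlation, and 1 of the 39 other lists was called. Apart from the shifted list, changed genes were picked from those with a mean of at least 1 CPM. The recovered shares do not cover genes below that level. Each gene was drawn independently around 1 mean for all groups. The simulated counts thus held no correlation between genes, no infection effect and no outlying library. These rates therefore may not carry over to the real libraries, above all for the list tests.

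Alternatives were size factors of DESeq2 1.42.0, the DESeq2 Wald test, no filter on low counts, a minimum of 1 CPM in 9 libraries, limma with library weights, 2 surrogate variables from sva 3.50.0, the replicate number as a block (replicate block), only the groups compared, scores of lymphoid follicle and pancreatic genes as covariates, and the libraries without 1 that stood apart from its group by more than 4 median absolute deviations. Alternatives chosen after seeing the data were the follicle score as the only covariate, leaving out each of the 36 libraries in turn, and leaving out both libraries that were rich in follicle B cell RNA. For each contrast, 100 splits of the libraries were drawn, the real one included. No pair of libraries of the same group looked like copies, since chi-square per degree of freedom between any such pair was at least 21.9. Pairs from different groups were not checked.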

Results

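The small intestine of 36 female mice was profiled by RNA sequencing, with 9 mice in each of 4 groups. The mice ate a control diet or a clover diet from arrival, and in each diet 1 group was infected with Heligmosomoides polygyrus, a roundworm that lives in the small intestine of mice. Infected mice received about 300 larvae after 11 days of acclimatization, and all mice were killed 15 days after infection. Total counts ran from 32857189 to 41548253 (32.9 to 41.5 M) per library, with means ± SD of 38.1 ± 2.83 M in control mice, 38.5 ± 2.02 M in clover-fed mice, 38.8 ± 2.76 M in infected control-diet mice and 38.5 ± 2.57 M in infected clover-fed mice. Mitochondrial genes took 6.07 ± 0.600%, 6.54 ± 0.567%, 6.77 ± 0.832% and 7.27 ± 0.796% of the counts in the same order. The 10 most abundant genes of a library took 6.89 to 9.95% of its counts. The first principal component held 39.7% of the variance.

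Under the control diet, infection raised RNA of mucosal mast cells, tuft cells, type 2 cytokines and epithelial proteins that respond to worms. Mcpt1, a chymase of mucosal mast cells, went from 1.69 ± 1.27 to 388 ± 303 CPM, a log2 fold change of 7.84 ± 0.54 (adjusted p = 1.65e-12, higher in 9 of 9 infected libraries than in any uninfected one). Alox5, which starts leukotriene synthesis and is high in tuft cells, went from 2.96 ± 0.430 to 29.9 ± 14.6 CPM. Pla2g4c, a phospholipase of infected epithelium, went from 5.99 ± 8.03 to 3221 ± 3532 CPM. In the other direction Mgam, a brush border enzyme that digests starch, fell from 5117 ± 1364 to 2357 ± 892 CPM. In all, 1865 of 15149 genes passed, 1189 higher and 676 lower, of which 434 and 80 changed at least 2-fold.

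All 25 measured members of the tuft cell list rose with infection under the control diet, with a median log2 fold change of 2.57. They included Il17rb, the receptor for interleukin 25 (2.29 ± 0.16), Avil, which encodes the actin-binding protein advillin (2.57 ± 0.22), Siglecf (3.07 ± 0.26) and Alox5 (3.34 ± 0.28). Of 16 mast cell genes 14 rose, and 15 when adjusted over the list alone, with a median of 3.85. Cma2 (9.90 ± 0.64), Mcpt2 (7.77 ± 0.50) and Mcpt9 (6.71 ± 0.48) encode proteases of this cell. Of 20 type 2 genes 14 rose, and 16 when adjusted over the list alone. They included the cytokines Il13 (6.56 ± 0.88) and Il5 (3.41 ± 0.57) and Gata3, the transcription factor of T helper 2 cells (2.46 ± 0.23). Of 18 genes of parasite-induced epithelial effectors 11 rose, with 11 higher and 1 lower when adjusted over the list alone. They included the gasdermins Gsdmc2 (4.24 ± 0.44), Gsdmc3 (4.24 ± 0.43) and Gsdmc4 (3.81 ± 0.37), whose close similarity lets them share reads. These 4 lists passed camera with the preset correlation and also with an estimated correlation, at adjusted p = 0.0294 for tuft cells, 0.0476 for mast cells, 0.043 for type 2 genes and 0.0309 for the effectors. Without both libraries rich in follicle B cell RNA none of the 4 passed with an estimated correlation, at 0.0557, 0.0816, 0.0816 and 0.0604 in the same order. When 1 library was left out they passed that test in 35, 8, 28 and 34 of 36 fits.

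Genes of the gut wall and of myeloid cells rose beside them. Of 22 genes of alternatively activated macrophages and eosinophils 18 rose, and 19 when adjusted over the list alone (adjusted p = 0.0976 with an estimated correlation). Ccl8, a chemokine, rose by 4.39 on the log2 scale, Mgl2, a lectin of macrophages, by 1.79 and the matrix protein Fn1 by 1.53. Chil3, a chitinase-like protein, had no counts in any uninfected control-diet library and was at least 2812-fold higher in infected mice, against a floor of 3 counts over the group. Gsdmc had 2 counts in the uninfected group, which gave a ratio of 1372 (95% interval 379 to 11332), and Rnase2a, an eosinophil-associated ribonuclease, a ratio of 389 (107 to 3221) from 2 counts. Of 21 smooth muscle genes 19 rose, and 20 when adjusted over the list alone (adjusted p = 0.115 with an estimated correlation), among them the contractile proteins Actg2 (1.75 ± 0.27), Cnn1 (1.35 ± 0.22) and Des (1.26 ± 0.22). Of 24 fibroblast and matrix genes 13 rose, and 19 when adjusted over the list alone (adjusted p = 0.311 with an estimated correlation), such as the collagens Col5a2 (0.99 ± 0.24) and Col3a1 (0.87 ± 0.24). Duox2 (3.96 ± 0.55) and Duoxa2 (4.63 ± 0.66), which form an epithelial hydrogen peroxide-producing enzyme, and the lectin Reg4 (2.54 ± 0.39) were among 9 of 21 antimicrobial genes that rose, while 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.259 with an estimated correlation). Among lymphocytes, 6 of 20 T cell genes rose, and 14 when adjusted over the list alone (adjusted p = 0.242 with an estimated correlation), including the intraepithelial integrin Itgae (0.87 ± 0.18). Of 11 plasma cell genes 6 rose, and 7 when adjusted over the list alone (adjusted p = 0.242 with an estimated correlation), including Jchain, which joins polymeric antibodies (0.57 ± 0.10). Of 17 MHC class II genes 7 rose, with the same count adjusted over the list alone (adjusted p = 0.311 with an estimated correlation), and of 28 genes of the interferon gamma response 5, and 6 when adjusted over the list alone (adjusted p = 0.532 with an estimated correlation). The type I interferon list went the other way and passed camera as lower with the preset correlation. It missed that test without both libraries rich in follicle B cell RNA (adjusted p = 0.0511). Of 23 genes of fetal-like and wound-associated epithelium 6 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.529 with an estimated correlation).

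Some genes of detoxification, digestion and cell division fell under the control diet. Of 33 xenobiotic metabolism genes 8 fell and 1 rose, with 13 and 1 when adjusted over the list alone (adjusted p = 0.311 with an estimated correlation). Aldh1a1, which makes retinoic acid, changed by -1.08 ± 0.26, and the efflux pump Abcb1a by -1.25 ± 0.36. Of 30 targets of NRF2, a transcription factor of the antioxidant response, 10 fell and 7 rose, with 11 and 7 when adjusted over the list alone (adjusted p = 0.367 with an estimated correlation). The glutathione transferases Gsta1 (-2.63 ± 0.43) and Gsta4 (-1.70 ± 0.24) fell and the glutathione peroxidase Gpx2 rose (1.51 ± 0.27). Of 28 enterocyte genes 3 fell, and 2 when adjusted over the list alone (adjusted p = 0.625 with an estimated correlation), which were Mgam (-1.12 ± 0.21), Sis (-0.74 ± 0.25) and the microvillus protein Vil1 (-0.38 ± 0.12) over all genes. Of 30 proliferation genes 10 fell, and 15 when adjusted over the list alone (adjusted p = 0.242 with an estimated correlation), including Tk1 (-0.42 ± 0.09) and Aurkb (-0.39 ± 0.09). Of 25 lipid absorption genes 7 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 0.532 with an estimated correlation), and of 23 endoplasmic reticulum stress genes 4 fell, also when adjusted over the list alone (adjusted p = 0.504 with an estimated correlation). Goblet cell genes split, with 8 of 23 higher and 4 lower, and 10 and 6 when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.298). The largest falls were those of Dmp1 (-3.05 ± 0.39), Gsta1, Gsta5 (-2.43 ± 0.57), B3galt5 (-2.27 ± 0.59), the vitamin C transporter Slc23a1 (-2.15 ± 0.55) and Serpina1f (-2.09 ± 0.53).

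The test was edgeR's quasi-likelihood test in all 36 libraries. With scores of follicle B cell and pancreatic acinar genes as covariates 291 genes passed, 245 of them among the 1865. Calls for Sis and Vil1 were lost in 25 and 10 of 36 fits that left out 1 library. The acinar list itself moved with infection, with 4 of 11 genes higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 0.0976 with an estimated correlation).

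**Figure D1:**
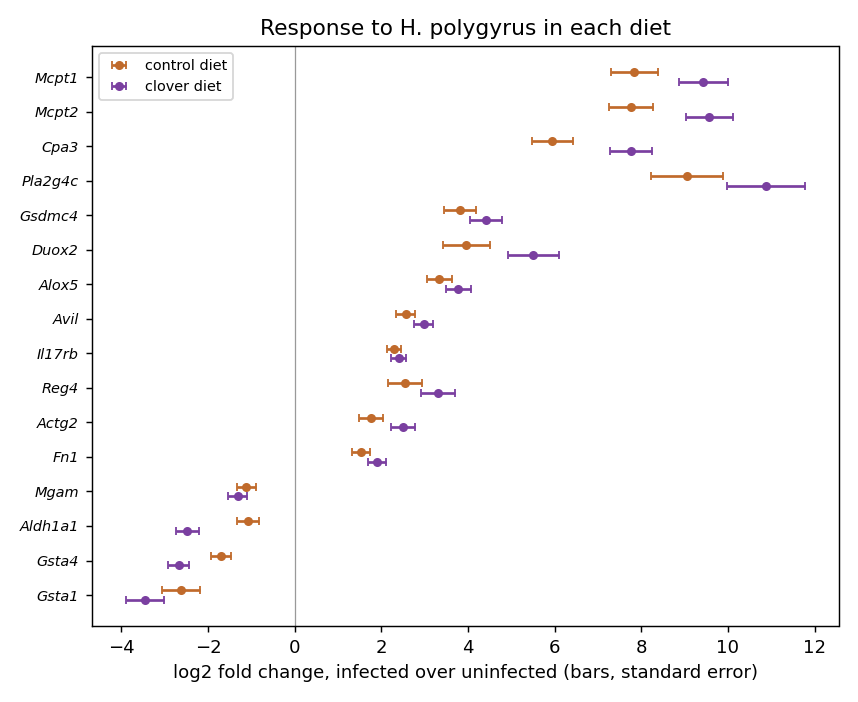
Log2 fold change with infection (horizontal axis) of 16 genes under the control diet and under the clover diet, as points with bars of ± 1 SE from edgeR, 9 libraries per group; Hp stands for H. polygyrus. Mast cell, tuft cell and epithelial genes lie above 0 and Mgam, Aldh1a1, Gsta4 and Gsta1 below 0 under both diets.

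Under the clover diet, infection raised mast cell and tuft cell genes and lowered genes for detoxification and fat handling, although no list passed camera with an estimated correlation (lowest adjusted p = 0.1). Mcpt1 went from 2.71 ± 1.34 to 1873 ± 1306 CPM, a log2 fold change of 9.44 ± 0.57 (adjusted p = 2.51e-14, higher in 9 of 9 infected libraries than in any uninfected one). Actg2, a smooth muscle actin, went from 244 ± 43.3 to 1387 ± 582 CPM. Aldh1a1 fell from 263 ± 52.4 to 47.0 ± 19.4 CPM, and Gsta1 from 46.3 ± 23.7 to 4.15 ± 5.06 CPM. In all, 4973 genes passed, 2755 higher and 2218 lower, of which 904 and 281 changed at least 2-fold.

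Again all 25 tuft cell genes rose, with a median log2 fold change of 2.47 (adjusted p = 0.1 with an estimated correlation), among them Alox5 (3.78 ± 0.29), Avil (2.98 ± 0.22) and the prostaglandin D synthase Hpgds (1.80 ± 0.15). Of 16 mast cell genes 15 rose, with the same count adjusted over the list alone and a median of 6.81 (adjusted p = 0.1 with an estimated correlation), among them Cma2 (9.81 ± 0.57), Mcpt2 (9.57 ± 0.53) and Mcpt9 (7.60 ± 0.45). Of 20 type 2 genes 16 rose and 1 fell, with 17 and 1 when adjusted over the list alone (adjusted p = 0.1 with an estimated correlation), including Il4 (4.48 ± 0.63) and Gata3 (2.98 ± 0.24). Of 18 parasite-induced effectors 11 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Pla2g4c rose by 10.88 and Ang4, an antimicrobial ribonuclease, by 2.11. Goblet cell genes moved both ways, with 13 of 23 higher and 5 lower and the same counts adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). Retnlb, a goblet cell protein secreted against worms, rose by 9.20 and Clca1 by 1.56, whereas the secreted lectin Zg16 fell by 1.62. The eosinophil-associated Rnase2a had no counts in uninfected clover-fed mice and was at least 531-fold higher in infected ones, against a floor of 3 counts over the group.

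Immune and stromal lists also rose under the clover diet. Of those given below, all but the blood list had passed camera under the control diet too. The follicle B cell list also passed camera as higher under clover with the preset correlation, but it did not pass under the control diet with all libraries. Without both libraries rich in follicle B cell RNA, which were control-diet mice, it passed that test as higher under the control diet too (adjusted p = 0.00138). Of 28 genes of the interferon gamma response 24 rose, with the same count adjusted over the list alone (adjusted p = 0.268 with an estimated correlation), including the regulator Irf1 (0.58 ± 0.10) and the immunoproteasome subunit Psmb8 (0.85 ± 0.17). Of 17 MHC class II genes 11 rose, with the same count adjusted over the list alone (adjusted p = 0.286 with an estimated correlation), such as H2-Aa (1.05 ± 0.20). Of 20 T cell genes 15 rose, with the same count adjusted over the list alone (adjusted p = 0.268 with an estimated correlation), including Itgae (1.97 ± 0.18). Of 22 macrophage and eosinophil genes 20 rose, and 20 when adjusted over the list alone (adjusted p = 0.156 with an estimated correlation), including Ccl8 (5.78 ± 0.63). Smooth muscle genes rose in 20 of 21 cases, over all genes and adjusted over the list alone (adjusted p = 0.156 with an estimated correlation), with Actg2 at 2.51 ± 0.28 and Des at 1.95 ± 0.23. Of 24 fibroblast and matrix genes 20 rose, and 20 when adjusted over the list alone (adjusted p = 0.268 with an estimated correlation), such as Col5a2 (1.47 ± 0.24). Of 23 genes of fetal-like and wound-associated epithelium 14 rose and 4 fell, with 15 and 4 when adjusted over the list alone (adjusted p = 0.29 with an estimated correlation), among them the adhesion receptor Cd44 (1.41 ± 0.15). All 5 blood genes rose, also when adjusted over the list alone (adjusted p = 0.268 with an estimated correlation), with the globin Hba-a1 at 1.14 ± 0.25.

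Several metabolic lists held genes that fell under the clover diet. Of 33 xenobiotic metabolism genes 29 fell, with the same count adjusted over the list alone and a median log2 fold change of -1.46 (adjusted p = 0.156 with an estimated correlation), among them Aldh1a1 (-2.48 ± 0.27) and Abcb1a (-2.11 ± 0.36). Of 30 NRF2 targets 14 fell and 6 rose, with the same counts adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). The lower ones included Gsta4 (-2.68 ± 0.25), Gstm3 (-3.21 ± 0.39) and the aldo-keto reductase Akr1c13 (-1.72 ± 0.18). Of 28 genes of PPAR alpha and fatty acid oxidation 15 fell and 1 rose, with 17 and 1 when adjusted over the list alone (adjusted p = 0.286 with an estimated correlation). They included the fatty acid hydroxylase Cyp4a10 (-5.60 ± 0.94), the thiolase Acaa2 (-0.89 ± 0.15) and the mitochondrial importer of fatty acids Cpt2 (-0.51 ± 0.09). Of 25 lipid absorption genes 14 fell, with 18 lower and 2 higher when adjusted over the list alone (adjusted p = 0.268 with an estimated correlation), such as the fatty acid transporter Slc27a4 (-1.06 ± 0.17). Of 28 enterocyte genes 11 fell, and 13 when adjusted over the list alone (adjusted p = 0.354 with an estimated correlation), including Mgam (-1.31 ± 0.22), Vil1 (-0.64 ± 0.12) and Sis (-0.97 ± 0.25). Of 23 endoplasmic reticulum stress genes 10 fell and 1 rose, with 12 and 1 when adjusted over the list alone (adjusted p = 0.344 with an estimated correlation), among them the chaperone Hspa5 (-0.66 ± 0.12).

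With scores of follicle B cell and pancreatic acinar genes as covariates 779 genes passed edgeR's test, 686 of them among the 4973. The acinar score itself moved with infection. It was -0.155 ± 0.105 in uninfected clover-fed mice (highest 0.0168) and 0.407 ± 0.215 in infected ones (lowest 0.0651). Adjusting for it can thus also take out infection differences. With the follicle score as the only covariate 4666 genes passed. No list passed camera with an estimated correlation in this contrast, against 27 of 40 with the preset correlation and 27 by fry.

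Without infection, the clover diet went with slightly higher RNA of antioxidant and detoxification genes, although no gene passed over all genes tested. Akr1c13, an aldo-keto reductase, stood at 39.3 ± 10.4 CPM in control mice and 65.6 ± 19.6 CPM in clover-fed mice, a log2 difference of 0.74 ± 0.18, and the glutathione transferase Gsta3 differed by 0.88 ± 0.21 (adjusted p = 0.718 for both). Of 30 NRF2 targets 26 had a positive estimate, with a median log2 difference of 0.17, and 6 rose and 1 fell when adjusted over the list alone. The list passed camera at adjusted p = 2.26e-12 with the preset correlation and 0.00454 with an estimated correlation, and fry at 0.0151. Without both libraries rich in follicle B cell RNA the NRF2 list missed by fry (0.0633) and passed with an estimated correlation (0.0168). Gclc, which catalyses the first step of glutathione synthesis, differed by 0.38 ± 0.11 and Ugdh, which makes the donor for glucuronidation, by 0.33 ± 0.10. Of 12 targets of the aryl hydrocarbon receptor, a sensor of plant and microbial compounds, 11 had a positive estimate, with a median of 0.25, and 1 rose when adjusted over the list alone, Ugt1a7c (0.42 ± 0.11). That list passed camera with an estimated correlation (adjusted p = 0.013) and missed by fry (0.0581). Nqo1 (0.31 ± 0.11) and Gsta1 (0.88 ± 0.40) belong to both lists.

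Genes of interferon responses and antigen presentation lay lower in uninfected clover-fed mice by camera with the preset correlation. All 25 genes of the type I interferon response had a negative estimate, with a median of -0.47, and 0 passed when adjusted over the list alone (adjusted p = 0.133 with an estimated correlation). Ifit1bl1 differed by -1.05 ± 0.35 and the nucleic acid sensor Zbp1 by -0.99 ± 0.36. All 17 MHC class II genes had a negative estimate, with a median of -0.52, and 13 fell when adjusted over the list alone (adjusted p = 0.133 with an estimated correlation), such as H2-Eb1 (-0.52 ± 0.17). All 28 genes of the interferon gamma response had a negative estimate, with a median of -0.32, and 1 fell when adjusted over the list alone (adjusted p = 0.256 with an estimated correlation). Psmb8 had the smallest p of that list (-0.65 ± 0.17). All 21 follicle B cell genes had a negative estimate, with a median of -2.35, and 17 fell when adjusted over the list alone (adjusted p = 0.68 with an estimated correlation). Pax5, a B cell transcription factor, stood at 8.02 ± 23.3 CPM in control mice and 0.295 ± 0.145 CPM in clover-fed mice, and 1 control mouse, control 5, held most of that RNA. Without control 5 the follicle list no longer passed camera (adjusted p = 0.923), and the MHC class II score difference went from -0.444 to -0.248 (exact permutation p = 0.0161). Of 28 genes of PPAR alpha and fatty acid oxidation 24 had a positive estimate, and 2 rose when adjusted over the list alone (adjusted p = 0.256 with an estimated correlation). Cyp4a10 had the smallest p of all genes, at 3.67 ± 0.80, with 0.158 ± 0.131 CPM in control mice and 2.07 ± 1.90 CPM in clover-fed mice.

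For diet without infection edgeR called 0 genes, while 693 of 15149 had an unadjusted p under 0.05 where chance would give 757. DESeq2 called 0 and limma with library weights 1, Gsta3, which is also among the 5 genes with the smallest p by edgeR.

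**Figure D2:**
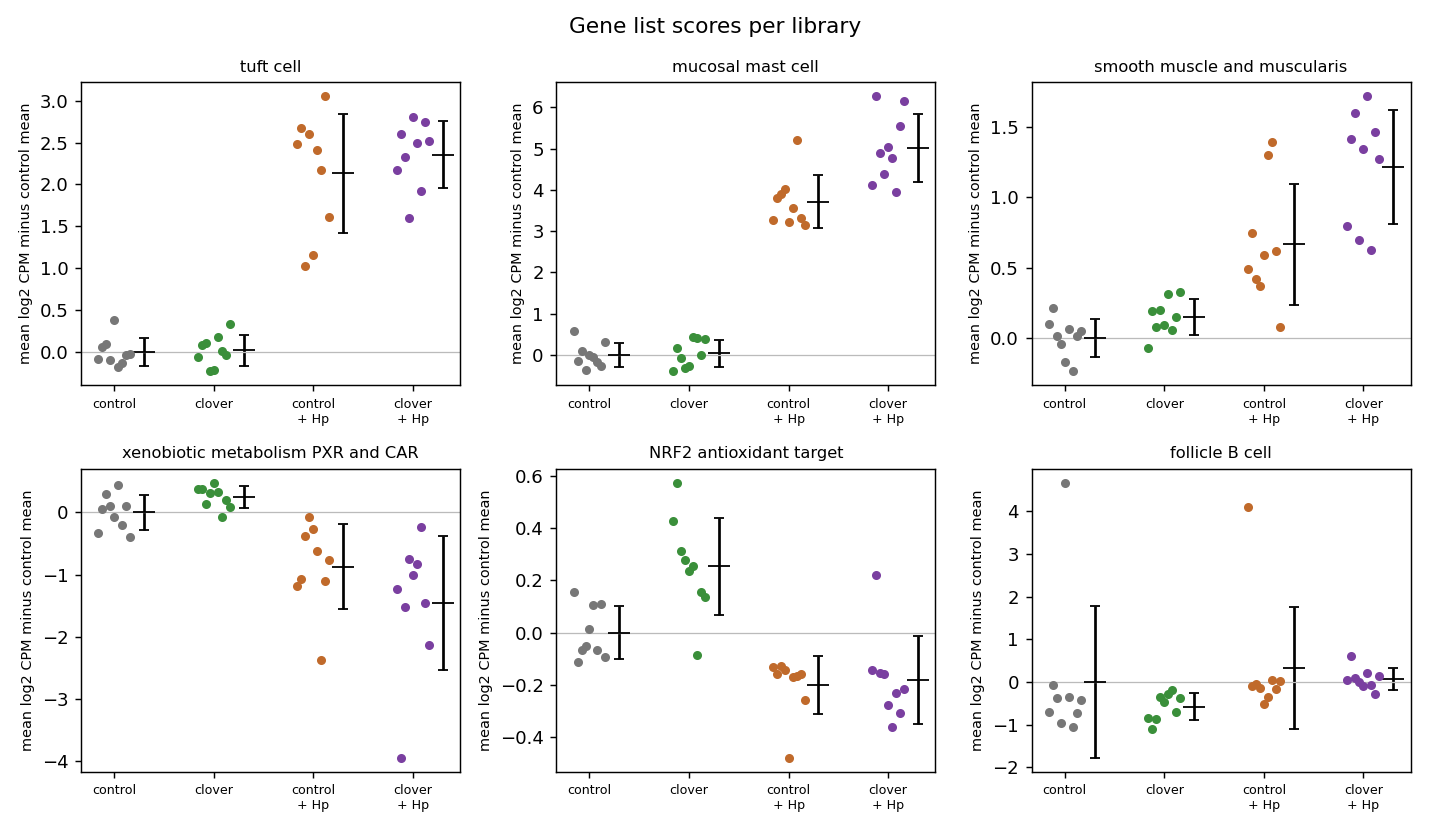
Score of 6 gene lists in each library (vertical axis, mean log2 CPM of the members minus the mean of uninfected control-diet mice), by group; points are the 9 libraries of a group, bars the mean ± SD, and Hp stands for H. polygyrus. Mast cell scores were 3.72 ± 0.640 in infected control-diet mice and 5.01 ± 0.831 in infected clover-fed mice, and a single uninfected control-diet library reached 4.67 for follicle B cells.

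Among infected mice, those fed clover had more mast cell RNA. Mcpt1 stood at 388 ± 303 CPM under the control diet and 1873 ± 1306 CPM under clover, a log2 difference of 2.27 ± 0.41 (adjusted p = 0.00337, with 6 of 9 clover-fed libraries above all 9 others). Fcer1a and Ms4a2, subunits of the high-affinity IgE receptor, differed by 2.42 ± 0.39 and 2.49 ± 0.46, and the proteases Mcpt2, Cpa3 and Mcpt9 by 2.09 ± 0.37, 2.06 ± 0.35 and 1.85 ± 0.32. Of 16 mast cell genes 7 rose, and 11 when adjusted over the list alone, with a median of 1.58. The list passed camera at adjusted p = 2.51e-20 with the preset correlation and 0.0416 with an estimated correlation, and fry at 0.000398. The score of the list was 3.72 ± 0.640 under the control diet and 5.01 ± 0.831 under clover, a difference of 1.29 (exact permutation p = 0.00251).

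In all, 45 genes passed for diet in infected mice, 40 higher and 5 lower, of which 26 and 0 differed at least 2-fold. Among genes with at least 1 CPM on average in 1 of these groups, the largest rises beside the mast cell genes were those of Uroc1, an enzyme of histidine breakdown (3.18 ± 0.51), the pepsinogen gene Pga5 (2.91 ± 0.50) and Tdrd5 (2.18 ± 0.48), all at 1.51 to 2.08 CPM under clover. The 5 lower genes were Pdlim2 (-0.59 ± 0.13), Hdhd3 (-0.44 ± 0.10), Blcap (-0.30 ± 0.06), Gorasp1 (-0.28 ± 0.06) and Ints4 (-0.24 ± 0.05). Of these and Tdrd5, the call was lost in 24 of 36 fits that left out 1 library for Hdhd3, 10 for Pdlim2, 8 for Gorasp1, 8 for Tdrd5 and 1 for Blcap (without infected control-diet mouse 5). Among the others, named after their values were seen, were Gata2, a transcription factor of mast cells (1.31 ± 0.24), Tph1 (1.25 ± 0.20) and Slc18a2 (1.14 ± 0.16), which make and store serotonin, Itgae (0.93 ± 0.18), and Ahrr, which represses the aryl hydrocarbon receptor (1.16 ± 0.23). All 21 smooth muscle genes had a positive estimate, with a median of 0.55, and 0 passed over all genes and 19 when adjusted over the list alone (adjusted p = 0.204 with an estimated correlation). The score of that list was 0.665 ± 0.428 under the control diet and 1.21 ± 0.405 under clover. All 5 blood genes had a positive estimate, and 5 rose when adjusted over the list alone (adjusted p = 0.347 with an estimated correlation). Of 33 xenobiotic genes 31 had a negative estimate, with a median of -0.45 and 0 passing when adjusted over the list alone (adjusted p = 0.599 with an estimated correlation). The score was -0.870 ± 0.688 under the control diet and -1.46 ± 1.08 under clover.

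The number of genes in this comparison moved with single libraries and with the tool. Leaving out 1 library gave 29 to 272 genes, with 272 without infected control-diet mouse 7, 131, 126 and 108 without infected clover-fed mice 7, 4 and 1, and 29 without infected clover-fed mouse 9; DESeq2 gave 140, including all 45, and a fit of these 2 groups alone 14. The mast cell list passed with an estimated correlation in 26 of 36 fits that left out 1 library, with adjusted p from 0.024 to 0.0852, and it missed without both follicle-rich libraries (0.1).

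Whether the response to infection differed between diets was tested by the interaction. Itga2b, the integrin alpha chain of platelets and of the mast cell lineage, was the gene that passed. It stood at 2.35 ± 0.522 CPM in control mice, 2.16 ± 0.512 CPM in clover-fed mice, 7.33 ± 2.10 CPM in infected control-diet mice and 24.2 ± 11.8 CPM in infected clover-fed mice, an interaction of 1.84 ± 0.31 on the log2 scale (adjusted p = 0.0126). The next smallest p were those of Tph1 (1.32 ± 0.28), Slc18a2 (1.04 ± 0.22), Cpt2 (-0.54 ± 0.12) and Gp1ba, a platelet receptor subunit (2.22 ± 0.51), each at adjusted p = 0.207. Mast cell genes had positive interaction estimates in 14 of 16 cases, with a median of 1.03, and 0 passed over all genes and 7 rose when adjusted over the list alone (adjusted p = 0.411 with an estimated correlation). Of the 40 lists 22 passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry. By edgeR 881 genes had an unadjusted p under 0.05 where chance would give 757, and DESeq2 called 10 genes. Itga2b passed in each of 36 fits that left out 1 library (adjusted p from 0.00303 to 0.0337) and by DESeq2 (4.15e-05), but not by limma with library weights (1.70, adjusted p = 0.065), with 2 surrogate variables (1.71, 0.05) or without both libraries rich in follicle B cell RNA (1.82, 0.0502), nor in 1 further fit given in the closing section.

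The infection response as a whole was larger in clover-fed mice by a narrow margin. The infection score was 0.933 ± 0.359 in infected control-diet mice and 1.36 ± 0.481 in infected clover-fed mice, a difference of 0.429 (permutation p = 0.0492, 9 mice per group). An exact permutation test of the same difference within infected mice gave p = 0.0463. It held the uninfected mean of each diet fixed and left out the spread of uninfected mice, so it adds no separate support. Of 3151 genes that rose on average over both diets 2684 (85.2%) had a larger estimate under clover, with median log2 fold changes of 0.39 under the control diet and 0.61 under clover. Of 2804 genes that fell 2314 (82.5%) fell further under clover, with medians of -0.22 and -0.33. Both shares came from the genes and libraries of the infection score, so they restate its difference and are no further evidence. Across 15149 genes, which are not independent replicates, infection effects under both diets correlated at r = 0.883 (rho = 0.752). Both diets shared 1118 higher genes, where 216 would be shared if the calls were independent, and 544 lower genes, where 99.0 would, and 0 genes went opposite ways. Diet effects in uninfected and infected mice correlated at r = 0.202 (rho = 0.0852). Without infected clover-fed mouse 2, which stood apart from its group, the difference of the infection score was 0.321 (permutation p = 0.0878), and with rising genes only it was 0.250 (permutation p = 0.0595). With falling genes only it was 0.179 (permutation p = 0.0462).

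**Figure D3:**
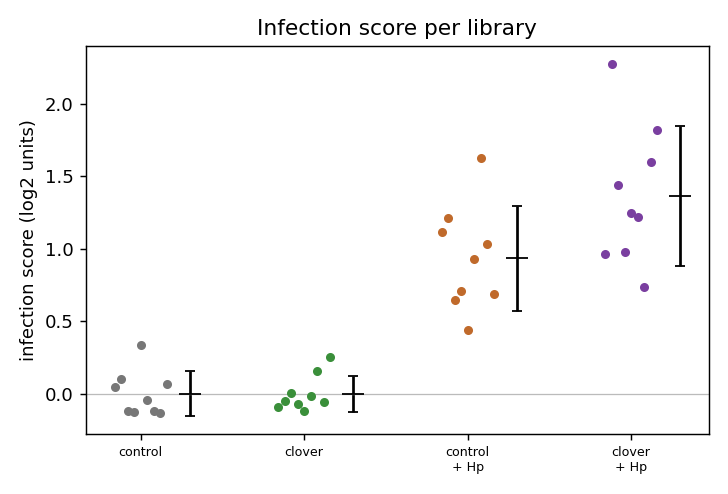
Infection score of each library (vertical axis, log2 units, 0 at the uninfected mean of its own diet) by group; points are the 9 libraries of a group, bars the mean ± SD, and Hp stands for H. polygyrus. Infected mice averaged 0.933 under the control diet and 1.36 under clover.

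Averaged over both diets, 5955 genes passed for infection, 3151 higher and 2804 lower. Averaged over infection states, 13 genes passed for diet, 11 higher and 2 lower. The 2 lower genes, named after their values were seen, were Gp2, a glycoprotein of exocrine pancreas and M cells, and Gpr141b. The count for diet ranged from 7 to 51 when 1 library was left out, with 51 without infected control-diet mouse 7 and 22 without infected clover-fed mouse 1. It was 7 without infected control-diet mouse 3 or infected clover-fed mouse 8, and 8 without control mouse 6 or infected control-diet mouse 1. With a replicate block it was 1, and without both libraries rich in follicle B cell RNA 4, with 0 lower genes in each of these fits.

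**Figure D4:**
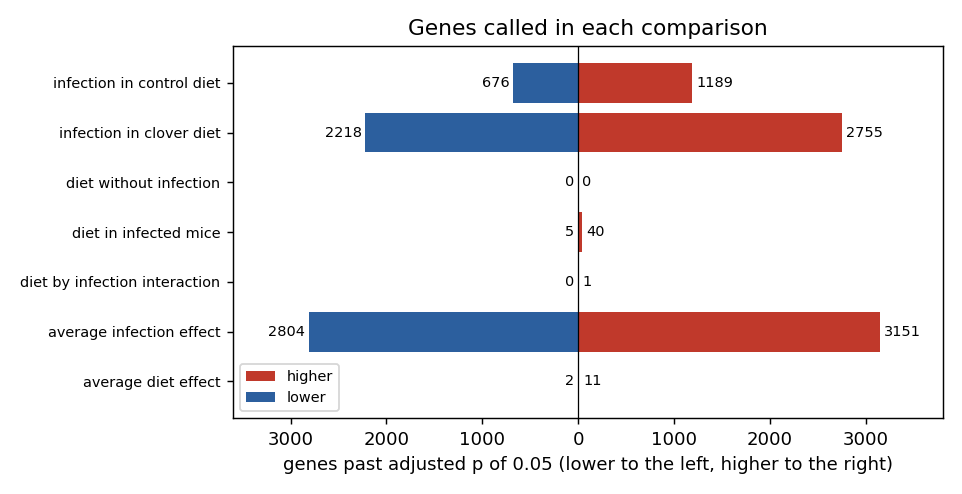
Number of genes past an adjusted p of 0.05 (bars from 0) in each of the 7 contrasts of edgeR, higher and lower shown apart, in 36 libraries. Infection under clover gave 4973 genes, infection under the control diet 1865, diet in infected mice 45, diet without infection 0 and the interaction 1.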

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

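The tests that left out each library in turn for the follicle B cell and MHC class II genes were chosen only after the result was seen, and the follicle score as the only covariate after the data were seen. Over 23 measures in each of 4 groups of 9 libraries, 19 values from 8 libraries lay far from the rest of their group by Dixon's test, where chance would give about 4.6 of 92.

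Uninfected control mouse 5 was highest in its group for follicle B cell genes, with a score of 4.67 against -1.06 to -0.0665 in the other libraries. It was also highest for MHC class II genes (1.57, others -0.448 to 0.259), tuft cell genes (0.386, others -0.174 to 0.101) and the infection score (0.334, others -0.131 to 0.101). Infected control-diet mouse 1 had the highest scores of its group for follicle B cell genes (4.11, others -0.507 to 0.0529) and MHC class II genes (1.77, others -0.0609 to 0.619). Infected control-diet mouse 7 had the highest mast cell score of its group (5.20, others 3.16 to 4.02), with 1155 CPM of Mcpt1 (others 124 to 455), 532 CPM of Mcpt2 (others 64.0 to 210.4) and 8.44 CPM of Fcer1a (others 1.26 to 4.31), and the lowest xenobiotic metabolism score (-2.38, others -1.18 to -0.0690). Infected control-diet mouse 9 had a type I interferon score of 0.827 (others -0.695 to -0.0343) and 197 CPM of Aldh1a1 (others 22.6 to 94.9). Infected control-diet mouse 5 had an NRF2 target score of -0.481 (others -0.259 to -0.129). Infected clover-fed mouse 2 had an NRF2 target score of 0.223 (others -0.363 to -0.145) and 17.1 CPM of Gsta1 (others 0.609 to 4.67). Control mouse 1 had 4.77% of its counts in mitochondrial genes (others 5.81 to 6.64) and 4.65 CPM of Mcpt1 (others 0.837 to 2.72). Control mouse 9 had 26.7 CPM of Pla2g4c (others 1.00 to 6.52). By tests of the difference between diets, the infection effect on Itga2b was larger under clover by 1.84 on the log2 scale and the infection score by 0.429.

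Mast cell genes were higher in infected clover-fed mice than in infected control-diet mice, with a score difference of 1.29 (exact permutation p = 0.00251). Adjusted for a response score made without mast cell genes the difference was 0.788 ± 0.210 (SE, permutation p = 0.00135). As far as a linear adjustment on an average score can tell, this argues against a larger infection response alone. A larger response may still contribute, since the adjusted difference was smaller. Left-out libraries argue against 1 library as the source, since the lowest difference was 1.14, without infected clover-fed mouse 2 (exact permutation p = 0.00452). Adjusted for the smooth muscle score the difference was 0.719 ± 0.356 (SE, permutation p = 0.0522), so more gut wall muscle in the piece of tissue may contribute and stays open. The smooth muscle score itself rose with infection. It was 0.149 ± 0.127 in uninfected and 1.21 ± 0.405 in infected clover-fed mice, and 0.665 ± 0.428 in infected control-diet mice relative to uninfected ones. Adjusting for it can thus also take out infection response, so this test cannot tell how much muscle a piece held. An effect of the clover diet on mast cells stays open as well, and mice sharing a cage could not be modelled.

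Follicle B cell and MHC class II genes had lower mean scores in uninfected clover-fed mice than in uninfected control mice. For follicle genes the score difference of -0.574 (exact permutation p = 0.523) was 0.00938 without control mouse 5 (exact permutation p = 0.953), so no fall was left without that library. Their mean spread within groups was 3.02 times the median of the other lists, at 5.70 and 4.58 times in uninfected and infected control-diet mice and 1.01 and 0.807 times in the clover-fed groups, so a lymphoid follicle in some pieces of tissue cannot be told apart from other sources with such libraries in the control diet only. For MHC class II genes the score difference of -0.444 (exact permutation p = 0.00897) was -0.248 without control mouse 5 (exact permutation p = 0.0161), which argues against that library as the whole source. With the follicle score as a covariate their median went from -0.519 to -0.293, between the bounds set for and against fewer follicle B cells in the piece, so that explanation and an effect of diet both stay open.

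Type I interferon genes were lower in uninfected clover-fed mice, with a score difference of -0.488 (exact permutation p = 0.0264). With the follicle score as a covariate their median went from -0.473 to -0.447, which argues against fewer follicle B cells. Without control mouse 8 the difference was -0.361 (exact permutation p = 0.0531), the smallest over left-out libraries, which argues against 1 library as the whole source although the p no longer passed. An effect of the clover diet may underlie it, but the list did not pass with an estimated correlation and cages could not be modelled.

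Splits of the libraries were drawn 100 times for each contrast, the real one included. In the infection contrasts no other split reached the real count, which is the smallest share that 100 splits can give. This argued against a chance division of single mice. It held for infection under the control diet (1865 genes, highest other split 21, 1 split as large) and infection under clover (4973, highest other 3867, 1 split as large). It also held for the average infection effect (5955, highest other 0, 1 split as large). The splits exchanged single mice, so differences between cages were not covered. For the interaction (1 gene, highest other 9, 4 splits as large) the share of splits lay under the bound set beforehand. The same held for the average diet effect (13, highest other 527, 2 splits as large). In both contrasts single splits gave more genes than the real one. With 100 draws such shares lie too close to the bound to exclude chance. Chance could not be excluded for diet in infected mice (45 genes, highest other 987, 6 splits as large). For diet without infection the real count was 0, so the splits could not inform on chance (0 genes by edgeR and by DESeq2, 1 by limma with library weights, 693 at an unadjusted p under 0.05, highest other split 1, 100 splits as large). The split with 3867 genes left 16 of 18 clover-fed mice with their own infection label. The counts of 987 and 527 came from the same split, which points to a structure of the samples: its arms of infected mice differed by -0.478 in infection score, against 0.429 for the real diets. No test was made of what sets those mice apart.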

How the results depend on the processing

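The follicle score as the only covariate, the fits without 1 library and the fit without both libraries rich in follicle B cell RNA were chosen after seeing the data. With follicle and acinar scores as covariates 291 genes passed for infection under the control diet, 779 for infection under clover, 965 for the average infection effect, 165 for diet in infected mice and 75 for the average diet effect. The acinar score itself moved with infection. With the follicle score alone 2009 genes passed for infection under the control diet, 4666 under clover and 5714 for the average infection effect. The DESeq2 test gave 140 for diet in infected mice, 10 for the interaction and 35 for the average diet effect. Limma with library weights gave 1 gene for diet without infection (Gsta3), 78 for diet in infected mice, 5 for the interaction (Aldh1a7, Amacr, Cpt2, Klk1b5 and Tph1) and 37 for the average diet effect. With 2 surrogate variables 102 genes passed for diet in infected mice and 0 for the interaction. With a replicate block 0 passed for the interaction (Itga2b 1.77, adjusted p = 0.146) and 1, Gbp2b, for the average diet effect. Replicate numbers did not pair libraries between groups: same-numbered libraries correlated at -0.0629 to 0.0553 on average, and 0 to 3 of 9 libraries of a group correlated best with their own number. A fit of only the groups compared gave 14 for diet in infected mice, and the follicle score as a covariate 76. Without both follicle-rich libraries 0 passed for the interaction and 4 for the average diet effect (Ccdc62, Gbp2b, Prnp and Slc18a2). The infection score difference was 0.321 (permutation p = 0.0878) without infected clover-fed mouse 2 and 0.250 (permutation p = 0.0595) with rising genes only, while with falling genes only it was 0.179 (permutation p = 0.0462) and still passed. The cause was not tested for these changes.

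Leaving out 1 library gave 1324 to 2317 genes for infection under the control diet, 4408 to 5240 for infection under clover, 0 to 0 for diet without infection, 29 to 272 for diet in infected mice, 1 to 3 for the interaction, 5642 to 6164 for the average infection effect and 7 to 51 for the average diet effect. For diet in infected mice the counts outside 1.5 times were 272 without infected control-diet mouse 7, 131, 126, 108 and 29 without infected clover-fed mice 7, 4, 1 and 9. For the interaction they were 3 without infected clover-fed mouse 1 (Itga2b, Slc18a2 and Tph1) and 2 without infected control-diet mouse 7 (Itga2b and Tph1). DESeq2 size factors, no filter and the stricter filter kept each count within 1.5 times.

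No named gene that passed turned direction in a setting. Of named genes that passed, the call held in every setting for 33 of 95 with infection under the control diet, 57 of 108 with infection under clover and 4 of 14 for diet in infected mice, and 61, 51 and 0 calls were lost with the follicle and acinar covariates. When 1 library was left out, 16, 2 and 5 of those genes lost the call at least once. Every list that passed camera did so with DESeq2 size factors, and no list passed in the opposite direction in these settings. Direction was counted only where a list passed. The follicle B cell list, lower by camera for diet without infection, had a median log2 difference of 0.0163 without both follicle-rich libraries. With 2 surrogate variables 24 of 24, 23 of 27, 14 of 18, 16 of 20 and 16 of 22 lists passed. These were for infection under the control diet, infection under clover, diet without infection, diet in infected mice and the interaction, in that order. In the same order 24, 25, 18, 14 and 16 passed without infected clover-fed mouse 2, 23, 27, 14, 17 and 22 without both follicle-rich libraries, and 24, 26, 14, 20 and 20 with the follicle score as a covariate.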

Other observations

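Other epithelial lists moved in parts with infection. Of 20 Paneth cell genes 4 rose and 7 fell under the control diet, with the same counts adjusted over the list alone (camera adjusted p = 0.612), and 9 rose and 6 fell under clover, with 10 and 6 when adjusted over the list alone (camera adjusted p = 0.177). Lyz1, the lysozyme of Paneth cells, fell under both diets (-0.81 ± 0.16 and -0.99 ± 0.17), whereas Ang4 rose under both (1.64 ± 0.18 and 2.11 ± 0.18). Of 19 stem cell genes 4 fell and 1 rose under the control diet, with 6 and 1 when adjusted over the list alone (adjusted p = 0.504 with an estimated correlation). Tnfrsf19 fell by 0.55 on the log2 scale, while Lgr5, the receptor that marks crypt base stem cells, stood at -0.53 ± 0.16 and missed the threshold in 4 of 36 fits that left out 1 library. Of 12 aryl hydrocarbon receptor targets 3 fell with infection under the control diet, and 4 fell and 1 rose when adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Nqo1, a quinone reductase, was among them (-0.55 ± 0.11), as was Nfe2l2, which encodes NRF2 (-0.49 ± 0.11). The same list had 4 lower genes under clover, and 6 when adjusted over the list alone (adjusted p = 0.156 with an estimated correlation). Of 16 genes of the proximal small intestine 2 rose and 2 fell with infection under the control diet, with 2 and 4 when adjusted over the list alone (adjusted p = 0.367 with an estimated correlation), and 3 rose and 7 fell under clover, with 3 and 10 when adjusted over the list alone (adjusted p = 0.324 with an estimated correlation). Among them were S100g, a calcium-binding protein of absorptive cells, higher under both diets (3.02 ± 0.41 and 3.03 ± 0.41) and the carboxylesterase Ces2g lower (-0.90 ± 0.26 and -1.57 ± 0.27).

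In uninfected mice, 15 of 18 circadian clock genes had a positive estimate under the clover diet, with 0 passing when adjusted over the list alone (adjusted p = 0.133 with an estimated correlation). All 21 smooth muscle genes also had a positive estimate, with a median log2 difference of 0.15 and 0 passing when adjusted over the list alone (adjusted p = 0.589 with an estimated correlation). Clovers hold isoflavones, plant compounds that can bind oestrogen receptors. The list of 16 oestrogen-responsive genes had 0 genes past the edgeR threshold for diet without infection and 0 for diet in infected mice. Adjusted over the list alone the counts were 0 and 0 (camera adjusted p = 0.971 and 0.909). Of all 15149 genes 0 and 45 passed in these contrasts, so the counts past the edgeR threshold say little about an oestrogen effect. Among infected mice, 26 of 30 proliferation genes had a positive estimate under clover, with 0 passing when adjusted over the list alone (adjusted p = 0.599 with an estimated correlation). Of 23 goblet cell genes 19 had a positive estimate, and 4 rose and 1 fell when adjusted over the list alone (adjusted p = 0.599 with an estimated correlation), with Spink4 at 0.84 ± 0.24 and Clca1 at 0.64 ± 0.19.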
